A study of Mus musculus with 18 samples.

How the data were processed

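Total RNA of 18 samples of mouse dorsal root ganglion explants was measured, each on 1 one-colour Cy3 Agilent array, for 3 days (0, 10 and 22 of myelination medium), 3 batches of ganglia and 2 arrays per batch and day. Per the labels, a batch is a pool of embryos collected at its own time and the 2 arrays are samples from the same batch. Each array held 62976 spots, 3671 of them controls. Per the file headers, the authors extracted the intensity of each spot with Agilent Feature Extraction 10.7.1.1 (10.7.1 per the submitters' processing notes), which subtracted background and removed spatial trends. The array design names the mouse build mm9, per the file headers. The other flag columns of 0 and 1 (well above background, saturated, not uniform, population outlier) come from the same software, per the file headers. The authors also deposited a value table of intensity on a linear scale. Its 18 columns have the same median, 33.7, and the same distribution, so the values were quantile normalized, and the steps are not given in the sources used here.

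Each column of the value table was set against every array file. Each of the 18 columns had a Spearman correlation of 1 with a single file, and at most 0.975 with any other, but for 12 columns that file stood under another sample of the same day, the same way on each day. The array files were kept under the sample they were filed with, and the fit was repeated with the batch that the value table gives each array.

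The main values were log2 of the processed intensity minus the 75th percentile of the array, over spots that were not controls (75th percentiles of 584 to 747). Spots marked as outliers, 93 to 181 per array, were left out, and 0 were saturated. Spots of a probe were averaged. A probe was kept where it was well above background on all 6 arrays of at least 1 day, which left 30432 of 55681 probes. The files hold accessions and no gene names, unlike what the design assumed. Accessions were matched without versions to a RefSeq gene table of assembly GRCm38.p6, which is not the build of the arrays, so no coordinates are given. In all, 26582 probes matched 20145 symbols, 1534 RefSeq probes did not match, and 4226 Ensembl, 16194 genome interval and 7145 other probes kept their own names. The brightest probe stood for each of the 5370 symbols with more than 1, which left 22855 features.

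Arrays of a batch and day were averaged, and limma 3.58.1 (lmFit and eBayes, R 4.3.3, with the package data.table at version 1.17.8) was fitted to the 9 values with the 3 days as groups. Adjusted p is Benjamini-Hochberg over the features, with a threshold of 0.05. Differences between batches within days were tested by limma's F test on the 18 arrays. The 23 gene lists covered peripheral myelin proteins, regulators of Schwann cell myelination, immature and repair Schwann cell genes, cholesterol biosynthesis, fatty acid and sphingolipid synthesis, cell cycle, nodal and axoglial junction genes, pan-neuronal and sensory neuron genes, basal lamina, fibroblast, perineurial, satellite glia, macrophage, endothelial, skeletal muscle, melanocyte and central glia markers, interferon-stimulated genes, complement and class I antigen presentation, hypoxia and glycolysis, the unfolded protein and stress response, and Charcot-Marie-Tooth orthologs. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and no camera call held with an estimated correlation. Some genes stand in more than 1 list, such as Pmp22, Gjb1 and Prx in the myelin and Charcot-Marie-Tooth lists. Scn9a, Cd68, Mx1 and Mx2 had no matched probe. Other members were on the array but did not pass the filter. That left 4 of 8 melanocyte, 4 of 10 central glia and 3 of 12 skeletal muscle markers tested.

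Genes were named by a rule: the 6 largest rises and 6 largest falls past the threshold with all batch values apart and all arrays of both days well above background, the 3 members past the threshold with the largest change in each called list, 11 fixed genes, and the 4 largest bounds per direction. For a gene well above background on all arrays of one day and none of the other, the dim day was set, per array, to the higher of the probe's own signal and the lowest signal well above background, and the fold is given as at least that. The design, the lists, the naming rule and the alternatives not named below as later choices were fixed before the data were examined.

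The replicate numbers mark a shared batch in the labels. Deviations from the day means of samples with the same number had correlations of -0.13 to 0.37 across genes, 6 of 9 above 0.1, and of -0.08 to 0.46, 8 of 9 above 0.1, with the batches of the value table. Tested on simulated data of 22829 genes, the fit recovered 37.3, 82.1 and 98.5% of genes changed 1.5-, 2- and 4-fold from day 0 to day 10, 53.7, 86.6 and 97.0% from day 10 to day 22, and 50.7, 77.6 and 93.9% from day 0 to day 22, with 6, 12 and 8 false calls. The simulated noise was independent and had the spread of the fit with the batches of the array files. These rates therefore do not cover the batches of the value table. The batch test recovered 194 of 200 genes simulated with batch differences of SD 2 (log2), with 11 false calls. In the data the median SD between batch means was 0.15, or 0.18 with the batches of the value table. Recovery of differences of that size was not tested.

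Alternatives were quantile normalization, normexp (offset 50) with quantile normalization, the authors' value table, no filter and a stricter filter, the mean of probes, outlier spots kept, the batch or slide as a block, all arrays with a random block, 1 technical array only, a trended and robust eBayes, fits over 2 days, and leaving out each batch. Normexp ran on median signals, since the mean signal named in the design is not in the files used here. Batches of the value table, single slides and leaving out an array with a low spike-in signal were chosen after seeing the data.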

Results

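Messenger RNA was measured in explant cultures of mouse dorsal root ganglia, in which sensory neurons, Schwann cells and the other cells of the ganglion are grown together and the Schwann cells form myelin once a myelination medium is given. Cultures came from pools of C57BL/6J embryos and were collected just before the medium was added (day 0), at early myelination (day 10) and when mature sheaths were abundant (day 22). Each day had 3 batches of ganglia from different pools of embryos, and each batch had 2 arrays that the labels call technical, giving 6 arrays per day and 18 in all. Each array held 59305 spots that were not controls, of which 54.8 to 61.5% were well above background, and the number of arrays limits the precision. The arrays lay on 3 slides, and slides 1 and 2 each held arrays of all 3 days. Levels are log2 intensities relative to the 75th percentile of the array. Changes are log2 differences ± the standard error of the limma fit to 9 batch values, n = 3 batches per day. In all, 22855 features were tested, 14543 of them genes with a RefSeq symbol. The series has no culture kept without the myelination medium, so time in culture and the medium cannot be told apart.

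The files placed the arrays in batches in 2 ways. Of the 18 columns of the authors' value table, 6 held the values of the array file of their own sample, and 12 held those of another sample of the same day. The days themselves were not affected. The batches of the array files were used throughout, as fixed beforehand, and each total and each count of a list is given again with the batches of the value table, which changes the spread but hardly the mean. Standard errors are those of the fit with the batches of the array files. If the value table has the right batches, each batch value averages arrays of 2 batches, and these errors can be too small. The median SD between batch means was 0.15 with the array files and 0.18 with the value table. A gene is said to have risen or fallen where it passed the threshold both ways. Since the batch numbers are shared across days, the batches of the value table were also fitted with the batch as a block, and this is given where it moved a count of a list by over 1.5 times or to or from 0, or changed the call of a gene named here.

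The first question was what changed between the start of myelination medium and early myelination. From day 0 to day 10 genes of peripheral myelin rose. Of the 15 myelin proteins fixed beforehand, 10 were higher (12 when adjusted over the list alone, 8 with the batches of the value table, 11 with the block as well) and 0 lower. Ncmap, a protein of noncompact myelin, rose by 5.02 ± 0.41 (adjusted p = 0.000294), the tight junction protein Cldn19 by 2.70 ± 0.30, the gap junction protein Gjb1 by 2.11 ± 0.33, and Pmp22, a protein of compact myelin, by 0.73 ± 0.16. Mbp, which is needed to compact the sheath, rose by 1.64 ± 0.17 on its brightest probe, whereas its 2 other probes had the opposite sign and the mean of its probes gave -0.23 (adjusted p = 0.235). Mag, an adhesion protein of the inner sheath, differed by 1.01 ± 0.25 (adjusted p = 0.0193, 0.0525 with the batches of the value table, and 0.0359 with the block as well). The list as a whole was higher by camera (adjusted p = 2.14e-07, and adjusted p = 0.365 with an estimated correlation).

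Lipid genes changed in part. In fatty acid and sphingolipid synthesis 6 of 23 members were higher and 1 lower (also 6 and 1 when adjusted over the list alone, 4 and 1 with the batches of the value table, 8 and 1 with the block as well). The largest rises were those of Fa2h, which hydroxylates fatty acids of myelin lipids (2.03 ± 0.29), the elongase Elovl7 (1.30 ± 0.18) and the phosphatidate phosphatase Lpin1 (1.02 ± 0.17). The list was called higher (adjusted p = 0.000385, and adjusted p = 0.426 with an estimated correlation). In cholesterol biosynthesis 0 of 20 members were higher and 1 lower, and the list was not called (adjusted p = 0.278).

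Genes of dividing cells fell. Of 23 cell cycle genes tested, 22 were lower (23 when adjusted over the list alone, 19 with the batches of the value table). Among them were Cdc20, an activator of the anaphase-promoting complex (-1.37 ± 0.14), the topoisomerase Top2a (-1.35 ± 0.30) and the spindle motor Kif11 (-1.32 ± 0.21). Mki67 differed by -1.26 ± 0.29 (adjusted p = 0.0143, and 0.0504 with the batches of the value table). The list was lower by camera (adjusted p = 1.00e-09, and adjusted p = 0.365 with an estimated correlation). Basal lamina genes were lower in 11 of 17 cases and higher in 1 (13 and 2 when adjusted over the list alone, 10 and 0 with the batches of the value table). They included the laminin chain Lama4 (-1.09 ± 0.10), the nidogen Nid2 (-0.98 ± 0.09) and Agrn, which encodes agrin (-0.97 ± 0.13). That list was called lower (adjusted p = 0.000465, and adjusted p = 0.365 with an estimated correlation). Of 19 genes of immature and repair Schwann cells 6 were lower and 1 higher (9 and 1 when adjusted over the list alone, 3 and 0 with the batches of the value table). The list was called lower (adjusted p = 0.0178, and adjusted p = 0.403 with an estimated correlation). The growth factor Gdnf fell by 1.17 ± 0.19, the cadherin Cdh2 fell by 1.17 ± 0.15 and the adhesion molecule Ncam1 fell by 0.90 ± 0.10. The low-affinity neurotrophin receptor Ngfr differed by -0.56 ± 0.16 (adjusted p = 0.0281, 0.0994 with the batches of the value table, and 0.0322 with the block as well). Egr2, the regulator of myelin genes (0.44 ± 0.40), Jun (-0.09 ± 0.14), Sox2 (-0.33 ± 0.18) and the neuronal tubulin Tubb3 (0.48 ± 0.17) did not pass the threshold.

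Immune genes were higher on day 10. Of 14 macrophage markers 11 were higher (12 when adjusted over the list alone), but 2 with the batches of the value table and 12 with the block as well. The lysozyme Lyz2 rose by 3.26 ± 0.38 and the Fc receptor Fcgr3 by 2.04 ± 0.36. The cathepsin Ctss differed by 1.98 ± 0.48 (adjusted p = 0.0164, 0.0734 with the batches of the value table, and 0.0113 with the block as well). Interferon-stimulated genes were higher in 11 of 15 cases and lower in 1 (12 and 1 when adjusted over the list alone, 6 and 0 with the batches of the value table, 10 and 0 with the block as well). Ifit1, well above background on 5 of the 6 arrays of day 0, rose by 1.89 ± 0.26. Oas1a, which senses double-stranded RNA, differed by 1.98 ± 0.43 (0.0111, 0.0645 and 0.0183). Complement and class I antigen presentation genes were higher in 13 of 15 cases (14 when adjusted over the list alone, 10 with the batches of the value table, 12 with the block as well). The complement factors C4b (3.01 ± 0.27) and C3 (1.70 ± 0.42) rose, as did Cfb, which was well above background on only 1 of the 6 arrays of day 0. Their camera calls had adjusted p = 1.56e-06, 2.53e-07 and 1.85e-10, each with adjusted p = 0.365 with an estimated correlation. Among named genes measured above background on all arrays of both days, the chemokine Ccl8 rose most (6.24 ± 0.28).

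Smaller groups moved too. Of 8 melanocyte markers 4 were tested and 3 were higher (also 3 when adjusted over the list alone, 2 with the batches of the value table). Dct, Mlana, Oca2 and Slc45a2 did not pass the filter on dim probes. The melanin enzyme Tyrp1 rose by 4.45 ± 0.39 and the transcription factor Mitf by 1.69 ± 0.12, while Pmel, 2.14-fold higher, passed only with the batches of the array files (adjusted p = 0.0130, and 0.0781 with those of the value table). In hypoxia and glycolysis 7 of 17 were higher (8 when adjusted over the list alone, 4 with the batches of the value table), and the peptide hormone Adm rose by 1.08 ± 0.16. The prolyl hydroxylase Egln3 (1.16 ± 0.31) and the hexokinase Hk2 (0.79 ± 0.17) passed only with the batches of the array files. Of 25 orthologs of Charcot-Marie-Tooth disease genes, a list that shares members with the myelin list, 7 were higher and 1 lower (also 7 and 1 when adjusted over the list alone, 6 and 0 with the batches of the value table, 6 and 1 with the block as well). The small heat shock genes Hspb1 (1.36 ± 0.20) and Hspb8 (1.16 ± 0.08) were among them. Camera called all 3 lists higher (adjusted p = 0.00303, 6.97e-05 and 0.0152), with adjusted p = 0.365, 0.365 and 0.426 with an estimated correlation. The melanocyte call was lost with no filter on dim probes (adjusted p = 0.156) and the Charcot-Marie-Tooth call with the second technical arrays only (0.0637). Fxyd6, a regulator of the sodium pump (4.68 ± 0.35), the prostaglandin synthase Ptgds (4.19 ± 0.76) and the carbonyl reductase Cbr2 (4.18 ± 0.42) rose. The extracellular matrix protein Spon1 fell by 3.17 ± 0.26, the synaptotagmin Syt13 fell by 2.95 ± 0.50, the RNA-binding protein Igf2bp3 fell by 2.76 ± 0.29 and Islr2 fell by 2.50 ± 0.40 (adjusted p = 0.0629 with the batches of the value table and the block). Hif3a (-2.42 ± 0.39) and Adamdec1 (-2.42 ± 0.41) passed only with the batches of the array files. Genes well above background on every array of one day and on none of the other have only a bound, the dim side being set to the lowest measurable level. The fibrinogen chain Fgb was at least 31.9-fold higher on day 10 (adjusted p = 0.000713), Cmtm2b at least 18.1-fold, the cytokine Il17b at least 13.3-fold and the oxidoreductase Xdh at least 8.94-fold. The elongase Elovl2 was at least 3.70-fold lower, Slitrk2 at least 3.12-fold, Uts2b at least 3.01-fold and Robo4 at least 2.54-fold.

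The remaining lists were not called from day 0 to day 10. Regulators of Schwann cell myelination had 1 member higher and 3 lower of 18 (adjusted p = 0.278), and nodal and axoglial junction genes 2 and 2 of 18 (0.466). Pan-neuronal genes had 0 and 0 of 16 (adjusted p = 0.159), sensory neuron genes 2 and 0 of 20 (0.0508) and the unfolded protein and stress response 0 and 3 of 14 (0.363). Among other cell types, fibroblast and fibrillar matrix markers had 3 higher and 4 lower of 16 (adjusted p = 0.908), and perineurial and barrier genes 3 and 1 of 9 (0.543). Satellite glia genes had 3 and 3 of 10 (adjusted p = 0.574), endothelial markers 3 and 1 of 10 (0.363), skeletal muscle markers 0 and 0 of 3 (0.653) and central glia markers 2 and 0 of 4 (0.151). The counts adjusted over the list alone were alike except for fibroblast markers (3 and 5), perineurial genes (3 and 2), endothelial markers (3 and 2) and cholesterol biosynthesis (0 and 0). With the batches of the value table the counts were 0 and 2 for regulators, 0 and 2 for the unfolded protein response, 2 and 2 for nodal genes and for fibroblast markers, and 1 and 3 for satellite glia genes. They were 1 and 0 for sensory neuron genes and central glia markers, 2 and 0 for endothelial markers, and 0 and 0 for cholesterol, pan-neuronal, perineurial and muscle genes. With the block as well 1 perineurial gene was higher and 1 endothelial marker lower. Nodal, fibroblast and perineurial genes had medians of -0.01, -0.20 and -0.18 but a mean and a camera direction above 0. With the replicate block the sensory neuron list was called higher (median 0.18, adjusted p = 0.0415), and Tubb3 passed the threshold (adjusted p = 0.0350).

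In the whole set 2605 features were higher and 4078 lower on day 10, 1083 and 721 of them by at least 2-fold. The batches of the value table gave 1347 higher and 1814 lower. Slide 1 alone gave 630 and 519, slide 2 alone 568 and 654, and the authors' own values, in the batches of the value table, 1530 and 1575. Of the calls 39.0% were higher with the batches of the array files, 42.6% with those of the value table and 49.3% with the authors' values in the latter. Without batch 1 of day 10 the counts were 1725 and 2696, and without its batch 2 the lower count was 2622.

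**Figure D1:**
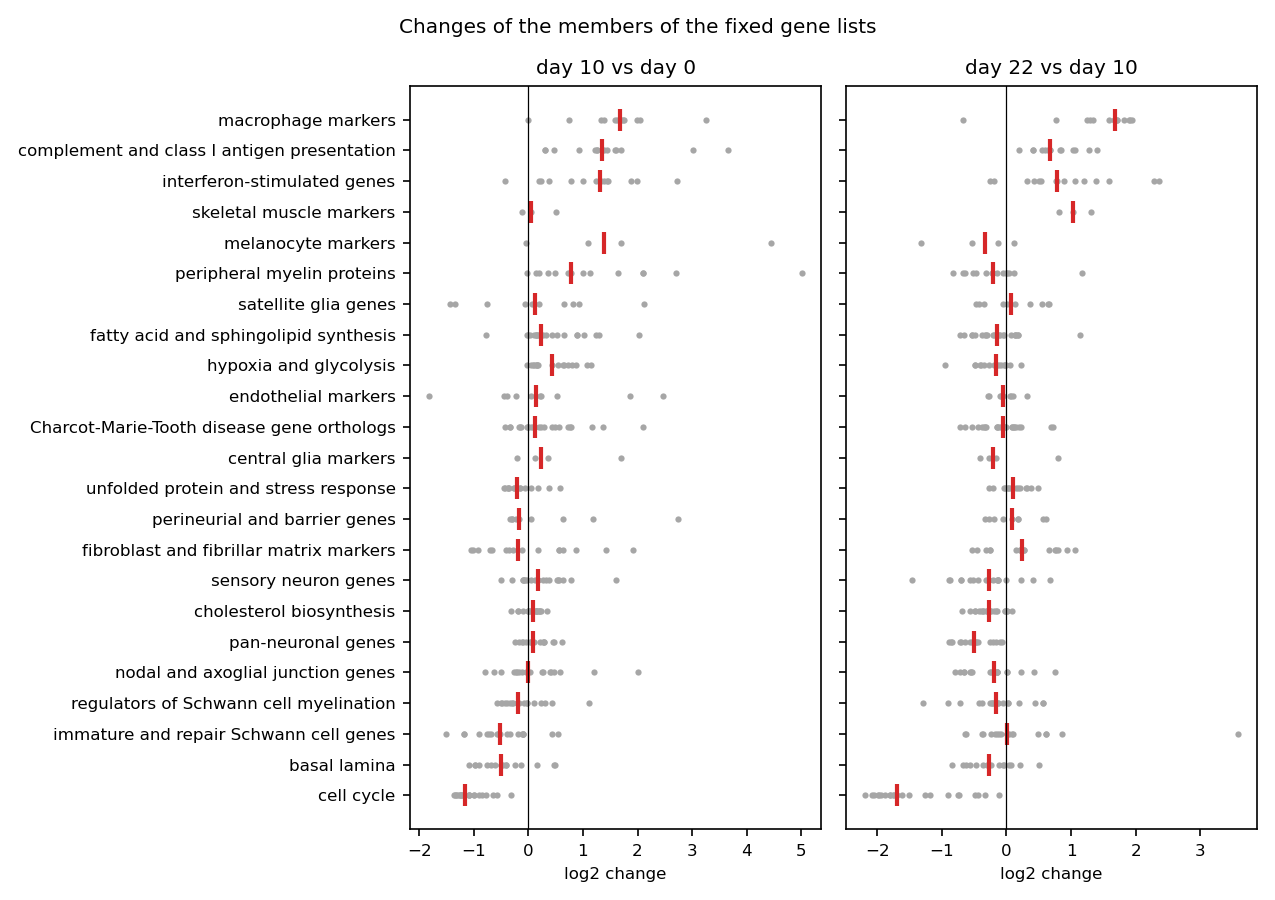
Log2 change of every tested member (grey points) of the 23 gene lists fixed beforehand, from day 0 to day 10 (left) and from day 10 to day 22 (right), with the list median as a red bar and lists ordered by their median change from day 0 to day 22. Cell cycle members lie below 0 in both panels, with medians of -1.15 and -1.69, and macrophage markers have medians of 1.67 in both.

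The second question was what changed as the sheaths matured. From day 10 to day 22 the cell cycle genes were lower again, in 22 of 23 cases (also 22 when adjusted over the list alone, 17 with the batches of the value table). Kif11, well above background on 5 of the 6 arrays of day 22, fell by 2.19 ± 0.21, the cyclin Ccnb1 fell by 2.08 ± 0.29, Top2a fell by 2.05 ± 0.30 and Mki67 fell by 1.99 ± 0.29 (camera adjusted p = 8.89e-19, and adjusted p = 0.442 with an estimated correlation). The repressors Mxd3 (-2.18 ± 0.18) and E2f7 (-2.15 ± 0.23) and the kinetochore protein Spc24 (-2.14 ± 0.15) were among the 6 largest falls measured above background on both days. Of 17 basal lamina genes 5 were lower (5 lower and 1 higher when adjusted over the list alone, 4 lower with the batches of the value table). The laminin chain Lama2 fell by 0.84 ± 0.10 and Nid2 fell by 0.68 ± 0.09. That list was called lower (adjusted p = 0.00979, and adjusted p = 0.612 with an estimated correlation), but not without batch 3 of day 22 (0.0741).

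The myelin list was not called in this interval (adjusted p = 0.240), with 1 of 15 members higher and 1 lower (1 and 2 when adjusted over the list alone, 0 and 0 with the batches of the value table, 0 and 2 with the block as well). Mbp differed by -0.23 ± 0.17, Mag by -0.68 ± 0.25, Pmp22 by 0.11 ± 0.16 and Egr2 by -0.73 ± 0.40, all short of the threshold, and the list was lower within slide 1 (median -0.64, adjusted p = 0.000872). Also short of it were Ngfr (-0.36 ± 0.16), Jun (0.03 ± 0.14), Sox2 (-0.24 ± 0.18) and Tubb3 (-0.25 ± 0.17). In cholesterol biosynthesis 1 of 20 members was lower (7 when adjusted over the list alone, 0 with the batches of the value table), the reductase Dhcr7 (-0.69 ± 0.16). The list was called lower (adjusted p = 0.00240, and adjusted p = 0.653 with an estimated correlation), a call lost within slide 2 (adjusted p = 0.0507). Its median went from -0.28 to -0.15 without batch 1 of day 22 (adjusted p = 0.0480).

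Macrophage markers were higher in 9 of 14 cases (11 when adjusted over the list alone), and interferon-stimulated genes in 8 of 15 (11 higher and 1 lower when adjusted over the list alone). Complement and class I genes were higher in 9 of 15 (12 when adjusted over the list alone). With the batches of the value table these counts were 0, 0 and 1, and with the block as well 8, 2 and 1. Lyz2 differed by 1.90 ± 0.38, Ctss by 1.94 ± 0.48, Fcgr3 by 1.91 ± 0.36, Oas2 by 2.36 ± 0.52, Oas1a by 2.29 ± 0.43, Ifit1 by 1.58 ± 0.26, C4b by 1.28 ± 0.27 and the complement protease C1s1 by 1.03 ± 0.23, each past the threshold with the batches of the array files but not with those of the value table. With the block as well Ctss, Fcgr3, Oas2 and Oas1a passed (adjusted p = 0.0346, 0.0352, 0.0322 and 0.0353), and the others did not. H2-D1, a class I molecule, rose by 1.06 ± 0.18 both ways (adjusted p = 0.0118 and 0.0431). The 3 lists were called higher (adjusted p = 4.83e-07, 4.83e-07 and 1.41e-08), with adjusted p = 0.543, 0.442 and 0.514 with an estimated correlation. The interferon call was lost with the second technical arrays only (adjusted p = 0.0838). Genes with larger rises included Vsig4, a complement receptor of macrophages (2.96 ± 0.42), and Sprr1a, a gene of regenerating neurons (3.00 ± 0.42). Fgb (3.62 ± 0.73), the resistin-like molecule Retnla (3.15 ± 0.62) and the granzyme Gzme (3.08 ± 0.56) passed only with the batches of the array files.

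Neuronal genes were lower as lists. Among 16 pan-neuronal genes 1 was lower, the synaptic vesicle protein Syt1 (-0.85 ± 0.20), and among 20 sensory neuron genes 2, among them the neuropeptide gene Tac1 (-0.89 ± 0.18). The counts were also 1 and 2 when adjusted over the list alone, 0 and 0 with the batches of the value table, and 1 and 1 with the block as well. Camera called both lists lower (adjusted p = 0.00123 and 0.0332), with adjusted p = 0.653 and 0.612 with an estimated correlation. The falls were uneven over arrays. Array means of the pan-neuronal list ran from 3.47 to 4.24 on day 22 and from 4.08 to 4.55 on day 10, and those of the cholesterol list from 3.16 to 3.81 and from 3.74 to 3.87. Array 1 of batch 1 on day 22 had the lowest mean of both lists and the highest of the macrophage markers (4.65, the others 2.50 to 4.42). Its means of the interferon list (1.36, the others -0.52 to 0.36) and the complement list (3.67, the others 2.49 to 3.18) were also the highest. Its myelin mean was the lowest (3.91, the others 4.56 to 5.15). Picked after their values were seen, both arrays of batch 1 and array 2 of batch 2 on day 22 had pan-neuronal means of 3.47, 3.51 and 3.61. Their cholesterol means were 3.16, 3.41 and 3.41, and their macrophage means 4.65, 4.09 and 4.42. The other arrays of day 22 ran from 4.08 to 4.24, 3.68 to 3.81 and 2.50 to 3.28 for these lists. Without batch 1 of day 22 the pan-neuronal median was -0.35 (adjusted p = 0.0156) against -0.51. The sensory call was lost with quantile normalization (adjusted p = 0.0534), the authors' values (0.0538), all arrays with a random block (0.0671) and the first or the second technical arrays only (0.0736 and 0.0551). It was also lost without batch 1 or 2 of day 10 or batch 2 of day 22 (adjusted p = 0.0567, 0.128 and 0.109), with the slide as a block (adjusted p = 0.0654) and within slide 1 (0.252). The hypoxia and glycolysis list was lower as well (adjusted p = 0.0332, and adjusted p = 0.653 with an estimated correlation). In it 2 of 17 members passed the threshold (4 when adjusted over the list alone, 0 with the batches of the value table), Ankrd37 (-0.94 ± 0.19) and Bnip3 (-0.48 ± 0.12). The call of Bnip3 was lost in most alternatives, such as quantile normalization (adjusted p = 0.0563), the replicate block (0.0638) and the batches of the value table (0.0533). The camera call of the hypoxia and glycolysis list was lost within slide 1 (adjusted p = 0.0507) and slide 2 (0.128). It was also lost with the batches of the value table and the block (0.0544). Without batch 1 or 3 of day 10 or batch 1 or 2 of day 22 the list call was lost too (0.0755, 0.0738, 0.0566 and 0.0831). So it was with the authors' values (0.0538), the first technical arrays only (0.148) and the array of low spike-in signal left out (0.0567). Of the 12 skeletal muscle markers 3 were tested and 1, the slow troponin Tnni1, was higher (1.30 ± 0.14, 2 higher when adjusted over the list alone, 0 with the batches of the value table, 1 with the block as well). The list was called higher (adjusted p = 0.0108, and adjusted p = 0.442 with an estimated correlation), a call lost within slide 2 (0.0507) and with no filter on dim probes (0.407). Among named genes measured above background on both days, Ly6h, a membrane protein of neurons, fell most (-3.30 ± 0.29). The synaptic organizer Lrrtm1 (-2.25 ± 0.19) and Camkv (-2.76 ± 0.65) were also lower. Serpina3m was at least 2.60-fold higher on day 22 and Stra6l at least 2.00-fold. Cacng5 was at least 3.36-fold lower, Lingo4 at least 1.90-fold and Kifc5b at least 1.80-fold. Myzap (at least 2.72-fold higher) and Vsnl1 (at least 3.18-fold lower) passed only with the batches of the array files, as did the laminin chain Lamc1 (-0.63 ± 0.10).

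The other lists were not called from day 10 to day 22. Regulators of Schwann cell myelination had 0 members higher and 3 lower of 18 (adjusted p = 0.283; 1 and 3 when adjusted over the list alone), and immature and repair Schwann cell genes 1 and 0 of 19 (0.677; 3 and 2). Fatty acid and sphingolipid synthesis had 0 and 2 of 23 (adjusted p = 0.321; also 0 and 2 when adjusted over the list alone) and nodal genes 0 and 1 of 18 (0.137; 0 and 1). Fibroblast markers had 0 higher and 2 lower of 16 (adjusted p = 0.467; 1 and 3 when adjusted over the list alone), and perineurial genes 0 and 0 of 9 (0.635; 0 and 0). Satellite glia genes had 1 and 0 of 10 (adjusted p = 0.411; 2 and 0 when adjusted over the list alone), endothelial markers 0 and 0 of 10 (0.782; 0 and 0), melanocyte markers 0 and 1 of 4 (0.304; 0 and 1) and central glia markers 1 and 1 of 4 (0.590; 1 and 1). The unfolded protein and stress response had 1 and 0 of 14 (adjusted p = 0.129; 1 and 0 when adjusted over the list alone) and Charcot-Marie-Tooth orthologs 1 and 0 of 25 (0.862; 0 and 0). With the batches of the value table each of these counts was 0, but for 1 fibroblast marker that was lower. With the block as well 1 central glia marker was higher and 1 gene of fatty acid and sphingolipid synthesis lower.

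This interval held the fewest calls, 960 features higher and 1241 lower, 403 and 384 of them by at least 2-fold. The batches of the value table gave 120 higher and 338 lower (26.2% of the calls higher against 43.6%), the batch as a block as well 317 and 399, slide 1 alone 214 and 262, slide 2 alone 14 and 32, and 96 and 335 (22.3%) came from the authors' own values in the batches of the value table. Leaving out a single batch gave 305 and 483 (day 10 batch 1), 391 and 667 (day 10 batch 2), 263 and 512 (day 10 batch 3), 323 and 587 (day 22 batch 2) or 1612 and 1883 (day 22 batch 3), and 806 lower without day 22 batch 1.

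**Figure D2:**
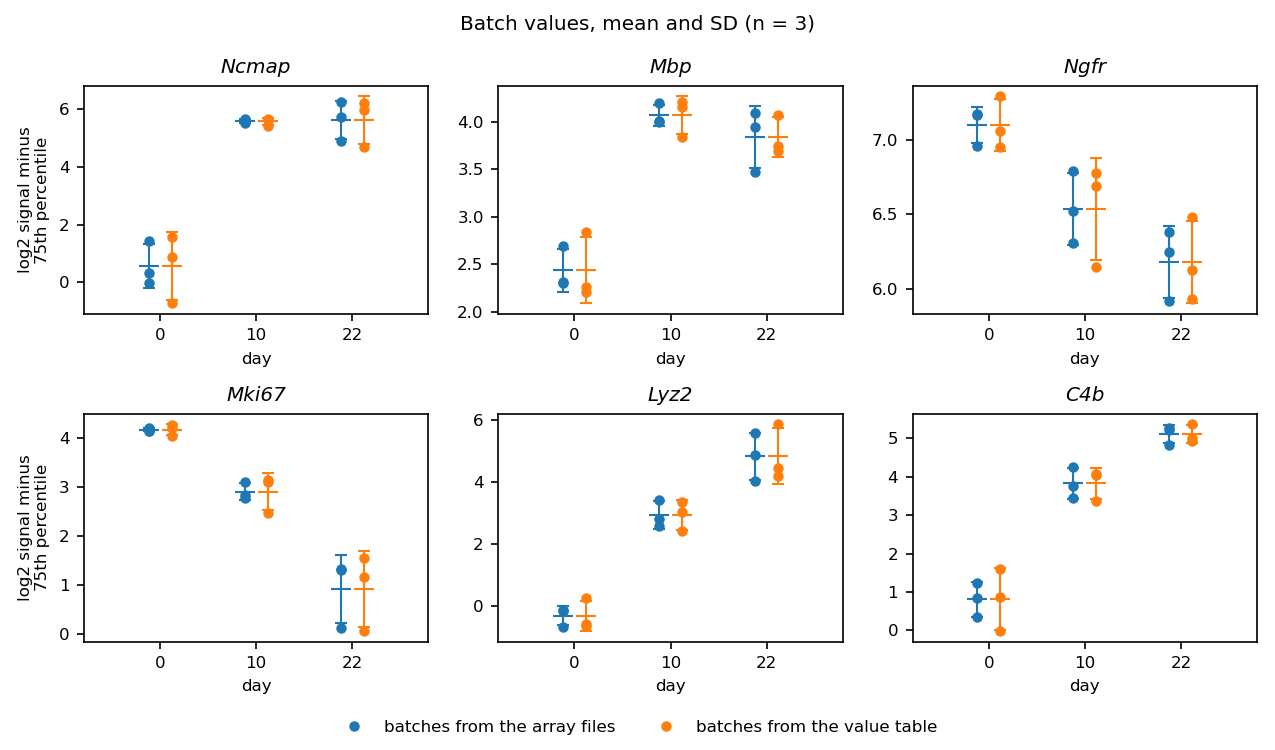
Log2 signal relative to the 75th percentile of each array for 6 genes on days 0, 10 and 22, with batch values as points and the mean and SD as bars (n = 3 batches). Blue uses the batches of the array files and orange those of the value table, which share their means, so that Mki67 falls from 4.18 to 0.93 in both and Ncmap goes from 0.57 to 5.63.

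The third comparison spans the whole course and is not independent of the other two. From day 0 to day 22 all 23 cell cycle genes fell both ways (also 23 when adjusted over the list alone, camera adjusted p = 4.82e-13, and adjusted p = 0.397 with an estimated correlation). Kif11 changed by -3.51 ± 0.21, Top2a by -3.40 ± 0.30 and Mki67 by -3.25 ± 0.29. Basal lamina genes were lower in 13 of 17 cases and higher in 1 (14 and 2 when adjusted over the list alone, 13 and 1 with the batches of the value table). Nid2 (-1.66 ± 0.09), Lama4 (-1.65 ± 0.10) and Lamc1 (-1.54 ± 0.10) fell most, and the list was called lower (adjusted p = 0.000929, and adjusted p = 0.397 with an estimated correlation).

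Immune genes were higher under both sets of batches. Macrophage markers were higher in 12 of 14 cases (13 higher and 1 lower when adjusted over the list alone), and interferon-stimulated genes in 12 of 15 (also 12 when adjusted over the list alone). Complement and class I genes were higher in 14 of 15 (15 when adjusted over the list alone), and the counts with the batches of the value table were 12, 12 and 14 (13, 12 and 14 with the block as well). Lyz2 rose by 5.15 ± 0.38, Fcgr3 by 3.95 ± 0.36, the cathepsin Ctss by 3.92 ± 0.48, Oas1a by 4.27 ± 0.43, C4b by 4.29 ± 0.27 and C3 by 3.11 ± 0.42. Oas2 and Cfb rose as well but were well above background on only 3 and 1 of the 6 arrays of day 0. Ifi44 was well above background on all 6 arrays of day 22 and on 0 of day 0, and was at least 4.0-fold higher (adjusted p = 0.000229). Camera gave adjusted p = 5.30e-08, 5.24e-08 and 1.49e-11 for these lists, each with adjusted p = 0.397 with an estimated correlation. Among named genes measured above background on both days the largest rises were those of Ccl8 (7.88 ± 0.28), Ptgds (6.69 ± 0.76), the chemokine Ccl6 (6.10 ± 0.40), the inhibitory Fc receptor Fcgr2b (5.74 ± 0.27), Wfdc17 (5.68 ± 0.32) and the retinol carrier Rbp4 (5.46 ± 0.55). Fgb was at least 392-fold higher on day 22, Vsig4 at least 66.1-fold, the oxidoreductase Xdh at least 56.0-fold and the collagenase Mmp13 at least 41.9-fold.

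Of the myelin list 7 of 15 members were higher (also 7 when adjusted over the list alone, 8 with the batches of the value table, 8 higher and 1 lower with the block as well). Ncmap rose by 5.06 ± 0.41, Drp2, a partner of periaxin, by 3.27 ± 0.27, Cldn19 by 2.23 ± 0.30, Mbp by 1.41 ± 0.17 (its 2 other probes again opposite, and -0.41 with adjusted p = 0.0344 for the mean of its probes) and Pmp22 by 0.84 ± 0.16. Mag (0.33 ± 0.25) was short of the threshold. The list was called higher (adjusted p = 0.00122, and adjusted p = 0.698 with an estimated correlation), which was lost within slide 1 (median 0.02, adjusted p = 0.160) and held within slide 2 (0.73, adjusted p = 1.11e-05). In fatty acid and sphingolipid synthesis 8 of 23 were higher and 2 lower (also 8 and 2 when adjusted over the list alone, 6 and 2 with the batches of the value table). Fa2h rose by 1.49 ± 0.29 and Elovl7 by 0.97 ± 0.18, and the desaturase Degs2, well above background on 1 of the 6 arrays of day 0, rose as well. This call (adjusted p = 0.0436, and adjusted p = 0.698 with an estimated correlation) was lost with the slide as a block (adjusted p = 0.0526) and within slide 1 (median -0.09, adjusted p = 0.868). It was also lost without batch 2 or 3 of day 0 (0.0667 and 0.0710) or of day 22 (0.0886 and 0.117). So it was with all arrays and a random block (0.0539), the authors' values (0.0583), no filter (0.0723), a stricter filter (0.0557) and the second technical arrays only (0.0645). Ngfr fell by 0.92 ± 0.16, and Sox2 differed by -0.57 ± 0.18, past the threshold only with the batches of the array files. Egr2 (-0.29 ± 0.40), Jun (-0.06 ± 0.14) and Tubb3 (0.23 ± 0.17) were not past it. Among named genes measured above background on both days, Ly6h (-4.56 ± 0.29), Islr2 (-4.26 ± 0.40), Camkv (-3.93 ± 0.65), E2f7 (-3.68 ± 0.23), Tspan18 (-3.59 ± 0.27) and E2f8 (-3.55 ± 0.27) fell most. The receptor Gpr17 was at least 18.0-fold lower, Cacng5 at least 14.3-fold, the cadherin Cdh7 at least 5.45-fold and Otop3 at least 4.43-fold.

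Of the lists not called from day 0 to day 22, regulators of Schwann cell myelination had 2 members higher and 10 lower of 18 (adjusted p = 0.183; also 2 and 10 when adjusted over the list alone) and immature and repair Schwann cell genes 3 and 12 of 19 (0.182; also 3 and 12). Both were called lower with no filter on dim probes (adjusted p = 0.0429 each). Cholesterol biosynthesis had 0 higher and 6 lower of 20 (adjusted p = 0.355; 0 and 5 when adjusted over the list alone), and nodal genes 3 and 4 of 18 (0.763; 3 and 4). Pan-neuronal genes had 0 and 4 of 16 (0.417; 0 and 4) and sensory neuron genes 3 and 3 of 20 (0.861; 3 and 3). Fibroblast markers had 5 higher and 6 lower of 16 (adjusted p = 0.742; 7 and 6 when adjusted over the list alone), and perineurial genes 3 and 1 of 9 (0.479; 3 and 1). Satellite glia genes had 4 and 2 of 10 (0.332; 4 and 2), endothelial markers 2 and 3 of 10 (0.539; 2 and 3), melanocyte markers 2 and 0 of 4 (0.157; 2 and 0) and central glia markers 1 and 1 of 4 (0.737; 1 and 1). Hypoxia and glycolysis had 4 and 1 of 17 (adjusted p = 0.142; 3 and 1 when adjusted over the list alone), the unfolded protein and stress response 3 and 4 of 14 (0.958; 3 and 4) and Charcot-Marie-Tooth orthologs 6 and 4 of 25 (0.157; 6 and 3). Skeletal muscle markers had 2 of 3 higher (adjusted p = 0.0547; 2 when adjusted over the list alone), and were called with the replicate block (median 1.19, adjusted p = 0.0490, and 0.0375 with the batches of the value table and the block). With the batches of the value table there were 2 higher and 5 lower regulators, 1 and 4 immature and repair genes, 0 and 1 cholesterol genes, 3 and 5 nodal genes, 0 and 3 pan-neuronal genes and 1 and 2 sensory neuron genes. Likewise there were 3 and 5 fibroblast, 0 and 1 perineurial, 3 and 2 satellite glia, 2 and 2 endothelial, 2 and 0 melanocyte, 1 and 1 central glia and 2 and 0 muscle genes. Hypoxia had 2 and 0, the unfolded protein response 2 and 2 and Charcot-Marie-Tooth orthologs 6 and 2. With the block as well 4 cholesterol genes and 5 pan-neuronal genes were lower, sensory neuron genes had 2 and 3 and perineurial genes 1 and 1. Fibroblast, perineurial, central glia, sensory neuron and unfolded protein genes had medians below 0 (-0.14, -0.12, -0.09, -0.15 and -0.10) but a camera direction above 0.

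In total 3910 features were higher and 6246 lower on day 22 than on day 0, 1649 and 1271 of them by at least 2-fold, and 2971 and 4396 with the batches of the value table. Within slide 1 alone 1989 were higher and 2538 lower, and within slide 2 alone 1910 and 2629. Over the 3 days together 9611 features differed between any of them (limma F test), and 5940 with the batches of the value table.

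The design also compared variation between batches with that between technical arrays. With the batches of the array files and the 3 days pooled, no more spread was seen between batches than between the arrays of a batch. The median SD over genes was 0.21 between technical arrays and 0.15 between batch means, and the median over genes of their ratio was 0.69. Averaging 2 arrays with no batch effect would give 0.71 for the true SDs. A median of ratios estimated from so few arrays can lie below that. The limma F test called 0 of 22855 features for a batch difference within days (1781 at an unadjusted p under 0.05). By day the ratio was 0.60, 0.68 and 0.78 on days 0, 10 and 22. On each day 0 features were called (846, 971 and 1913 at an unadjusted p under 0.05). Day 22 lay above 0.71, and the lower ratios of the other days do not rule out a batch effect. With the batches of the value table the SDs were 0.17 and 0.18, the ratio 1.04, and 1985 features were called (6, 40 and 0 within days 0, 10 and 22 alone).

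**Figure D3:**
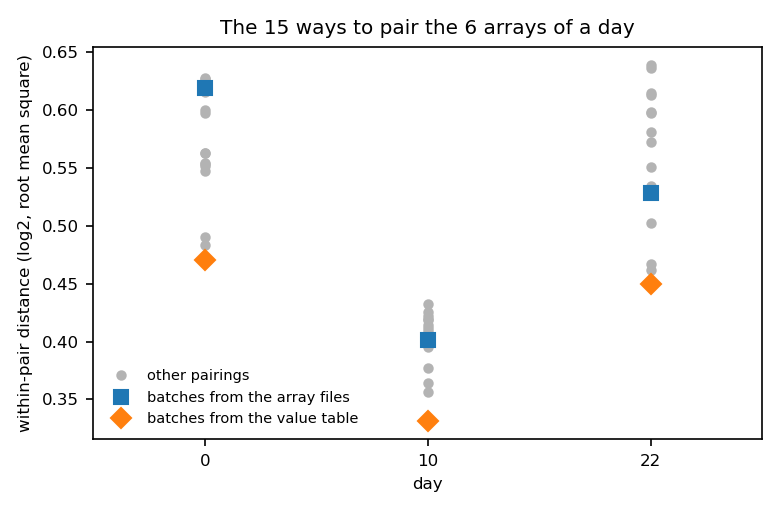
Within-pair distance (root mean square over genes, log2) for each of the 15 ways to pair the 6 arrays of a day, with the pairing of the array files as a blue square and that of the value table as an orange diamond. The value table's pairing is the closest on each day, at 0.47, 0.33 and 0.45, while that of the array files ranks 13, 7 and 5 from the closest on days 0, 10 and 22.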

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

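The tests of the batch placement were chosen only after the result was seen, as were the fit without the array of low spike-in signal and the splits with value-table batches or within batches, while the other splits of the samples were planned.

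Over 27 measures, 81 groups of 6 arrays were compared for a single array far from the other 5, which chance gives about 1 in 20 times, or 4.05 here, and 5 were found. Spike-in signal relative to the 75th percentile was -0.70 on day 0, batch 2 array 1, with the others at 0.40 to 0.81. On day 10, batch 2 array 1 the mean of the regulators of Schwann cell myelination was 2.82, with the others at 2.63 to 2.68. On day 22, batch 3 array 1 the cell cycle mean was -1.14, with the others at -0.16 to 0.29. On day 0, batch 1 array 2 the pan-neuronal mean was 3.51, with the others at 4.20 to 4.49, and the basal lamina mean was 5.57, with the others at 5.25 to 5.35. Without the array of low spike-in signal the counts were 2219 higher and 3352 lower on day 10 than day 0, and 717 and 1033 on day 22 than day 10.

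Array files and value table placed 12 of 18 arrays in different batches of the same day. Among the 15 ways to pair the 6 arrays of a day, the value table's pairing was the closest on each day (rank 1), which is what arrays filed under the wrong sample would give. Values standing under the wrong column would make that pairing arbitrary. The chance of such ranks on all 3 days is 0.000296 if the days are independent, which argues against wrong columns within limits. The placement was the same on each day, so an effect shared by the days is not covered. The criterion was also rewritten after the ranks were seen. A resemblance of arrays on 1 slide is also argued against, since same-slide pairs were no closer (mean distance 0.507, SD 0.123) than pairs across slides (0.498). It stays a hypothesis that the array files were filed under other samples of their day, which leaves the days as they are, and no biological explanation was tested.

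For each pair of days the 10 splits of the 6 batch values are too few for a share under 0.05. The real split was 1 of 10 with as many features, at 6683, 2201 and 10156 for days 10 and 0, 22 and 10, and 22 and 0, and the highest other split gave 0 in each. For a difference between any of the 3 days, 1 of 100 splits, the real one, reached 9611 and the highest other gave 6298, a split that left 7 of the 9 values with their own day. With the value-table batches the real split was again 1 of 100, at 5940 against 3409. With days exchanged only among values of one batch number, and the batch as a block, the real one was 1 of 36, at 9848 against 3322 with the array-file batches and 6380 against 1286 with those of the value table. In each of these 4 tests only the real split reached its count, a share under 0.05. Chance is thus an unlikely source of this count but is not excluded, and the 4 tests share the same arrays.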

How the results depend on the processing

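The value-table batches, the single slides, the fit without the array of low spike-in signal and normexp on median signals were tests chosen only after the data were seen, and the cause of a changed value was not tested except where stated. Below, pairs of counts are features higher and lower, for day 10 against 0, then 22 against 10, then 22 against 0, then features differing between any days. The authors' value table, which changes both the values and the batches, gave 1530 and 1575, 96 and 335, and 6008 for any day. No filter on dim probes gave 478 and 674 for day 22 against 10, 4 lists lower for day 22 against 0, and 5 features differing between batches within days. All arrays with a random block gave 1912 lower for day 22 against 10. Only the first technical arrays gave 455 and 400, 24 and 63, 1897 and 2528, and 2919, and only the second 1300 and 1918, 61 and 216, 2511 and 3764, and 4905, with fewer arrays by construction. The slide as a block gave 2087 and 2990 for day 22 against 10. The value-table batches gave 1347 and 1814, 120 and 338, 5940 for any day and 1985 between batches, with the replicate block as well 1698 and 2034, 317 and 399, and 6380, and with the slide as a block 2662 lower for day 10 against 0 and 343 and 717 for day 22 against 10. Slide 1 alone gave 630 and 519, 214 and 262, 1989 and 2538, and 3360, and slide 2 alone 568 and 654, 14 and 32, 1910 and 2629, and 3017. A fit over 2 days gave 554 higher for day 22 against 10. With an estimated correlation 0 lists were called in any comparison or direction. With the mean of its probes Mbp was -0.23 for day 10 against 0 and -0.41 for day 22 against 0, as its probes differ in sign. With the replicate block the counts were 2812 and 4042, 1196 and 1379, 4022 and 6426, and 9848, and the only calls it changed were those of Tubb3, Bnip3 and the sensory neuron and skeletal muscle lists given in the report. Leaving out each batch gave 1725 to 3083 and 2622 to 4485, 263 to 1612 and 483 to 1883, 3164 to 3998 and 4903 to 6279, and 7557 to 10154, with 8 to 10 lists higher and 3 to 3 lower, 4 to 5 and 4 to 7, and 4 to 6 and 2 to 2. Of 144 calls of named genes, quantile normalization kept 143, normexp 142, no filter 130, the value-table batches 110 and the same with the replicate block 120, and of 28 list calls they kept 27, 28, 25, 28 and 27. The fewest gene calls were kept by slide 2 alone (72), the first technical arrays (78), slide 1 alone (92), the second technical arrays (98) and the authors' value table (106), with 25, 26, 24, 24 and 25 list calls. Signal over background limits the bounds: between 54.8 and 61.5% of spots were well above it.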

Other observations

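All tests of hypotheses in this part were chosen only after the result was seen.

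Members of lists that were not called moved apart from each other between day 0 and day 22, and were picked here after their values were seen. Gldn, which gathers sodium channels at forming nodes, rose by 2.44 ± 0.24 and the axoglial adhesion gene Cadm3 by 0.69 ± 0.17, while the early nodal sodium channel Scn2a fell by 1.59 ± 0.17 and Cadm4, on the glial side, fell by 0.50 ± 0.09. The neuregulin receptor Erbb3 fell by 0.93 ± 0.17 and the adhesion receptor Adgrg6 fell by 0.79 ± 0.14, whereas Lgi4 rose by 0.43 ± 0.15. Among satellite glia genes the glutamine synthetase Glul rose by 0.96 ± 0.17, and Fabp7 fell by 1.91 ± 0.23. Each passed the threshold with both sets of batches (limma, n = 3 batches per day).

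Several posterior Hox genes, which mark the level of the body axis a cell came from, differed widely between arrays of one day. With levels under the lowest measurable one of an array set to it, the SD within days was 1.93 for Hoxa10, 2.05 for Hoxc10 and 2.33 for Hoxc9, with a median of 1.73 over 7 genes of groups 9 to 13 and 0.22 over all genes. A difference of the whole array is argued against by the median of 0.476 for 21 Hox genes of groups 1 to 8. The contrast holds for the medians and not for each gene. Without that bound, the SDs on days 0, 10 and 22 were 0.48, 0.23 and 0.69 for Hoxb9. They were 0.32, 0.86 and 0.72 for the dim Hoxc12. In groups 1 to 8 they were 1.30, 0.88 and 1.45 for Hoxd4 and 1.25, 0.78 and 1.19 for Hoxd8. Independent noise of dim probes is argued against by a median correlation between posterior genes of 0.296, above the 95th percentile of 1000 shuffled sets (0.128), although a bound of 0.5 written first was not reached and was replaced. Cultures taken from ganglia of different axial levels may remain as a hypothesis. Hoxa10 differed by at least 4.60 within a pair of arrays of 1 value-table batch (5.05 by the array files). It differed by over 2 in 2 of 9 such pairs (6 of 9). Arrays of day 0 with high Hoxa10 (-1.01 to -0.62) also had the highest fibroblast means (3.96 to 4.01, the others 2.70 to 3.36). Their perineurial means were highest too (0.98 to 1.06, the others -0.42 to 0.21). On day 10 the array with the highest Hoxa10 (-1.27) had a fibroblast mean of 3.71, below the 3.88 of another array. A difference in the share of cell types was not tested and cannot be told apart from axial level.

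Macrophage markers rose by a median of 3.36 from day 0 to day 22, with an SD over markers of 1.33. A loss of other cells that raises every remaining type alike is argued against, since the highest median among endothelial, fibroblast and satellite glia lists was 0.22. More macrophage RNA in the cultures is a candidate explanation, as 78.6% of the 14 markers (11) lay within 1 of the median. Lyz2, at 5.15 ± 0.38, lay outside that range, and 1 marker was lower when adjusted over the list alone. Whether the rise of interferon and complement genes came from macrophages alone cannot be told apart from a response of other cells: 10% of 30 such genes rose by more than the macrophage median plus SD by day 10 and 0 by day 22.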
